A study of Mus musculus with 6 samples.

How the data were processed

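The series holds 6 RNA-seq libraries of mouse P14 CD8 T cells, whose transgenic receptor recognises the gp33 peptide of lymphocytic choriomeningitis virus. Per the labels' protocols, cells spent 1 day with the peptide at 100 ng/ml and IL-2 at 1 ng/ml before being spun for 90 min at 32 °C and 2500 rpm with retrovirus, 8 ug/ml polybrene and 10 mM HEPES. They were cultured for 1 further day and then expanded for 2 days in 10 ng/ml IL-2. The viruses were MIG (an MSCV vector that carries GFP after an internal ribosome entry site, with no further insert), MIG-E47 and MIG-ID2. GFP-positive CD8 T cells were sorted, and polyadenylated RNA was sequenced. Each of the 3 groups has 2 libraries, described in the series as biological replicates.

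The deposited table gives, per the file headers, a raw fragment count and an FPKM value for each gene and library in the layout of Cuffdiff's read group tracking. Per the submitters' processing notes, TopHat2 2.1.1, Cufflinks 2.2.2 and Cuffdiff were used, and builds mm9 and mm10 are both named, with no word on which step used which. The raw fragment values are estimated counts made by the authors: 98.0% of 146058 values are exactly whole and 2918 are not, so they are expected counts and were rounded to whole numbers for the count models. The deposited FPKM values are fragments scaled to transcript length and to the mapped total as the authors computed them, and they were used only in alternatives. The table numbers the replicates of a group from 0, and replicate 0 was taken as the sample labelled replicate 1, which changes no group. In 10 genes, 12 values carry the status FAIL, and they were kept as listed.

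The table holds 24343 genes, of which 7550 have no fragment in any library. Total fragments per library ran from 17587185 to 24297069. For lower bounds of folds only, a zero count was set to a floor of 3 fragments per library, which is 0.123 to 0.171 CPM (counts scaled to a common library total). The count models used the rounded counts with their zeros. Intervals of ratios and floors cover counting error only, at a confidence of 95%. Where a gene had 0 fragments in a group, its fold is given as a lower bound against that floor. Where it had 1 to 3 fragments, the ratio is given with its counting interval. Whether counting used strand is not given in the sources used here, so fragments of overlapping antisense genes cannot be separated. Positions come from GRCm38 with GENCODE M21, which need not be the authors' annotation.

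Differences were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which kept 12524, and scaled by TMM with factors of 0.953 to 1.029. The quasi-likelihood F test was run on a fit over all 6 libraries with group as the only term. The Benjamini-Hochberg adjustment covered all tested genes, and a gene was called at an adjusted p under 0.05. The common dispersion was 0.0103, a biological coefficient of variation of 0.102. Levels are CPM after TMM scaling, given as mean ± SD of 2 libraries, and each log2 fold change is given ± its standard error. Unless another test is named, adjusted p-values of genes come from this edgeR test.

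There were 29 gene lists, fixed with 628 genes before the data were examined. The test covered 523 of these genes, 95 were under the filter and 10 were not found in the table under the listed name. A set of 28 lists had at least 3 tested genes and was tested with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The list of erythroid and platelet markers had too few tested genes. Named genes followed a rule fixed before the data were examined. It takes Tcf3 and Id2, 16 anchor genes of CD8 T-cell differentiation, and up to 8 named genes with the largest rise and 8 with the largest fall among called genes with a mean of at least 50 normalised fragments in the higher group and no overlap between groups. It adds the 3 most changed called members of each list that camera called, or its most abundant member where none was called, and the most abundant gene of each list of other cell types. Results of some genes are not reported here, and these genes have no rows in the sensitivity table, because they are withheld for evaluation. Further list members are named as examples and were chosen after their values were seen.

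The steps were tested on simulated counts drawn from the real means and library sizes, with 200 changed genes. These were drawn only from genes with a mean of at least 50 normalised fragments, so recovery was not measured for genes with fewer. A further planted list was raised 1.5-fold and counted neither as recovered nor as false. For MIG-E47 against MIG, 59.7% of genes changed by 1.5-fold, 89.6% of those changed by 2-fold and 100% of those changed by 4-fold were recovered, with 16 false calls among 192. For MIG-ID2 against MIG these shares were 47.8%, 94% and 100%, with 12 false calls among 186. For MIG-ID2 against MIG-E47 they were 50.7%, 89.6% and 100%, with 12 among 188. The simulated counts had the same spread in each group. In the real libraries only 6 genes were called for MIG-ID2 against MIG. With so few calls the adjusted p asks for a smaller unadjusted p, so the simulated recovery need not hold for that comparison. Both comparisons with MIG use the same MIG libraries, so their relation was set beside 50 simulations that held the fitted E47 change and no ID2 change.

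Alternatives were DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), other scalings, other filters, a fit on the compared groups alone, a replicate block, and each library left out in turn. With 1 library left out, the lone library of its group is assumed to vary like the other groups. Lists were also tested with camera at an estimated correlation and with fry, which asks whether the genes of a list move, on balance, one way. Tables and plots were made with Python 3.11.15 and matplotlib 3.10.9.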

Results

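RNA abundance was measured in activated mouse CD8 T cells carrying an empty GFP retrovirus (MIG), a virus encoding E47 (MIG-E47) or a virus encoding ID2 (MIG-ID2), with 2 libraries per group. E47 is a basic helix-loop-helix E protein encoded by Tcf3, and ID2 binds E proteins and keeps them from DNA. The libraries held 20951946 and 21737254 fragments for MIG, 20527851 and 17587185 for MIG-E47, and 24297069 and 20195840 for MIG-ID2. Between 14654 and 15112 genes had a fragment in a library. The first principal component held 87.1% of the variance and set the MIG-E47 libraries (90.5 and 74.48) apart from the other 4 (−42.24 to −39.51). The second held 5.2% and set MIG replicate 2 (−28.74) apart from the rest (−7.43 to 10.7). The MIG replicates differed more than the others: their counts varied 27.66 times as much as counting error, against 11.51 for MIG-E47 and 5.48 for MIG-ID2.

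The comparison of MIG-E47 with MIG asks which genes respond to added E47. Expression differed broadly with E47: 3565 of 12524 tested genes changed (28.5%), 2221 higher and 1344 lower. Increases were the larger ones. Of the 1411 genes that changed at least 2-fold, 1202 rose and 209 fell, and at least 8-fold differences were found in 473 genes that rose and in 1 that fell. Of genes tied to E proteins in lymphoid development 14 of 23 rose, as did Id1, Id2 and Id3, while Il7r, Ccr7, 14 of 31 effector genes and 12 of 22 glycolysis genes fell. With upper-quartile scaling, where the median log2 fold change of all genes was −0.118 against −0.018 with TMM, 4162 genes were called and 45.8% of them were higher, against 62.3% with TMM. Without MIG-E47 replicate 1, 1736 genes were called.

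Tcf3 (chromosome 10, 80409514 to 80433647, minus strand) was at 2450 ± 476 CPM with E47 and 219 ± 21.3 CPM in MIG, a log2 fold change of 3.48 ± 0.15 (adjusted p = 1.36e-06). Its fragments can come from the vector as well as from the cells' own gene. Id2 (chromosome 12, 25093799 to 25097140, minus strand) rose from 86.5 ± 16.6 to 320 ± 11.6 CPM (1.89 ± 0.15, adjusted p = 2.59e-05). Its relative Id3 rose from 36.5 ± 0.143 to 166 ± 14.3 CPM (2.19 ± 0.13, adjusted p = 6.84e-06). Among the anchor genes, Il7r, the receptor of the survival cytokine IL-7, fell by 0.94 ± 0.13 (adjusted p = 0.000802). The lymph node homing receptor Ccr7 fell by 0.99 ± 0.12 (adjusted p = 0.000277) and the effector transcription factor Tbx21 by 0.75 ± 0.13 (adjusted p = 0.00296). The pore-forming protein gene Prf1 rose from 11.9 ± 1.99 to 30.8 ± 1.18 CPM (1.37 ± 0.19, adjusted p = 0.000726). Bach2, a repressor of effector genes, was at 20.4 ± 0.54 against 33.4 ± 9.13 CPM (−0.71 ± 0.17, adjusted p = 0.0132). Without MIG-E47 replicate 1 or 2 its adjusted p was 0.0872 and 0.0847. Not called were Tcf7 (−0.08), Eomes (−0.15), Bcl2 (−0.34), Gzmb (−0.22), Prdm1 (−0.12) and Zeb2 (−0.13), although without MIG replicate 1 Bcl2 reached an adjusted p of 0.0101 and Gzmb one of 0.0268. Klrg1, Ifng and Cx3cr1 had at most 9 fragments per group in these groups and were not tested. In each called anchor gene, both MIG-E47 libraries lay on the same side of both MIG libraries.

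**Figure D1:**
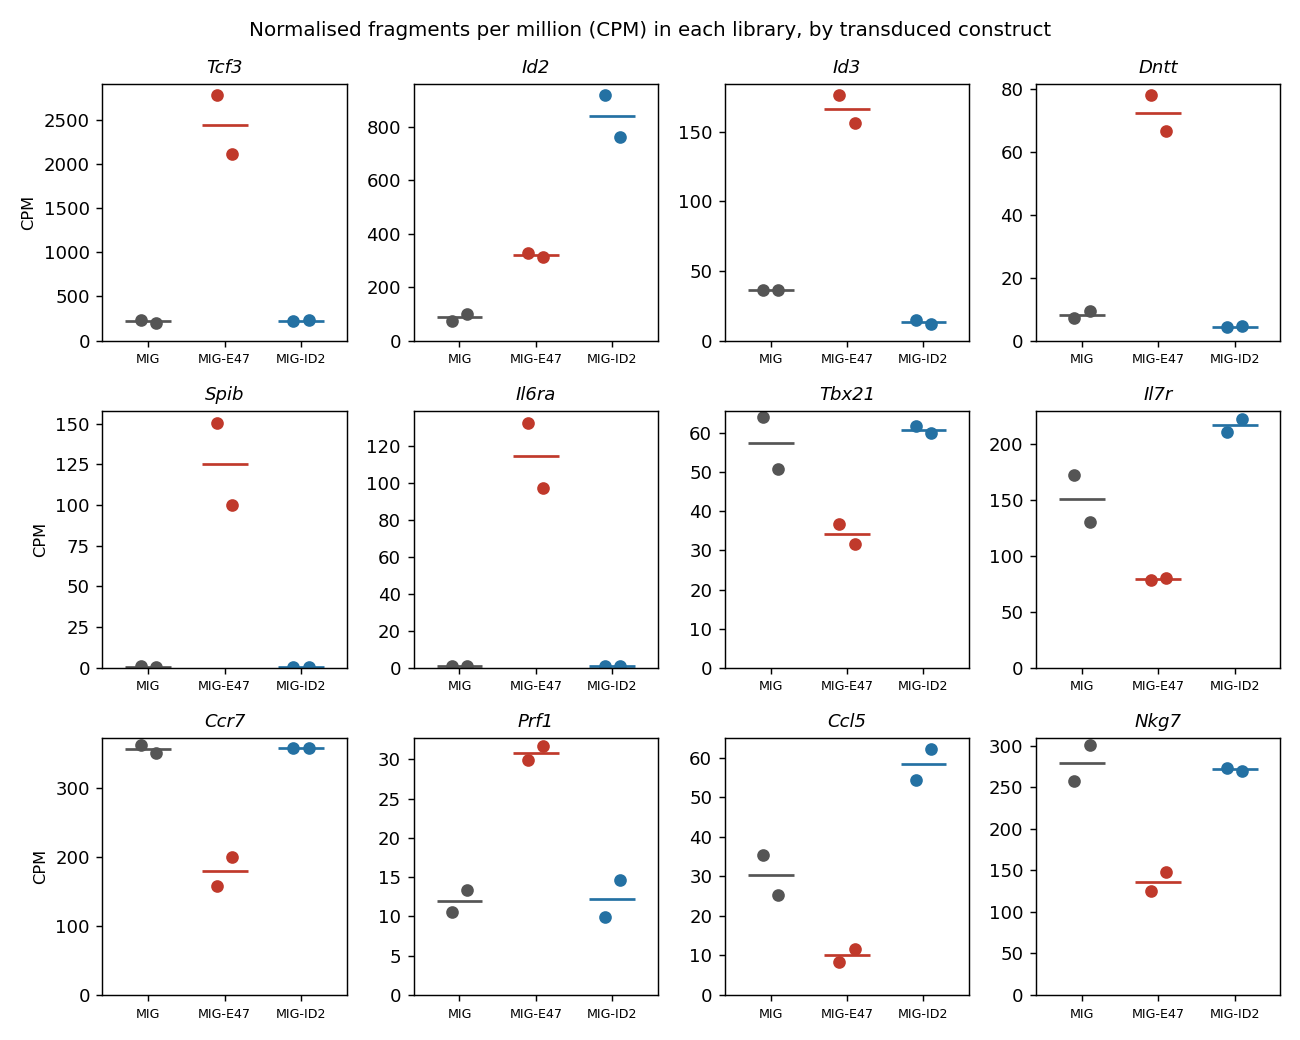
CPM of 12 genes in each of the 6 libraries, by group, on linear axes from 0 that differ between panels, with points for libraries and lines for group means. Both MIG-E47 libraries lie above both MIG libraries for Tcf3, Id2, Id3, Dntt, Spib, Il6ra and Prf1 and below them for Tbx21, Il7r, Ccr7, Ccl5 and Nkg7.

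A set of 125 genes without a fragment in either MIG library rose with E47, and no gene that fell was at 0 with E47. Ppl, which encodes the epithelial plakin periplakin, reached 212 ± 62.4 CPM, at least 1470-fold higher than in MIG (adjusted p = 1.36e-06). Col17a1, a hemidesmosome collagen, reached 59.2 ± 42.4 CPM, at least 409-fold higher, and at least 202-fold without MIG-E47 replicate 1 and 617-fold without replicate 2. Higher too were the POU-domain factor gene Pou3f1 by at least 369-fold, the calcium-binding protein gene S100a16 by at least 330-fold and the lipid droplet protein gene Cidea by at least 313-fold. Crb2, a cell polarity gene, was at least 229-fold higher, and Bglap3 at least 259-fold, although its fragments may be shared with the near-identical osteocalcin genes. Eps8l2, a regulator of actin, had 6203 fragments against 1, a ratio of 6760 (1210 to 267000). Adjusted p-values of the last 7 genes ran from 1.36e-06 to 0.000328, and each was higher in both libraries. The named decreases were smaller. Fxyd7, an ion pump regulator, was at −2.02 ± 0.29 (adjusted p = 0.000932) and the chemokine gene Ccl5 at −1.61 ± 0.2 (adjusted p = 0.000408). Fam183b (−1.71), Qrfp (−1.65), Spns3 (−1.62) and Grin1 (−1.62) also fell. Rec8 (−1.88, and −2.48 to −0.87 with libraries left out, adjusted p = 0.0344) was not called without MIG replicate 1 (0.187), MIG-E47 replicate 1 (0.216) or MIG-E47 replicate 2 (0.112), nor with limma-voom (0.0884).

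Of 23 tested genes associated with E proteins in lymphoid development, 14 rose, 3 fell and 6 were not called (15 rose and 3 fell adjusted over the list alone), with a median log2 fold change of 2.14 (camera adjusted p = 2.68e-10, and adjusted p = 0.881 with an estimated correlation). With libraries left out in turn the median was 1.29 to 2.02, as up to 25 genes of the list were then tested, and on the same 23 genes it was 1.88 to 2.24. Without either MIG-ID2 library it was 1.29, without MIG replicate 1 1.31 and without MIG-E47 replicate 2 1.41. Rag1, which cuts antigen receptor genes, had 1016 fragments against 1 (ratio 1110, 198 to 43800), and the Notch target Hes1 had 707 against 1 (771, 138 to 30500). The transcription factor gene Spib rose from 0.698 to 125 CPM (7.48 ± 0.29), and Dntt, which adds bases at receptor gene joins, from 8.22 to 72.4 CPM (3.14). Of 18 basic helix-loop-helix and Id factors, 9 rose, 4 fell and 5 were not called (10 and 5 adjusted over the list alone), with a median of 0.57 (camera adjusted p = 0.000184, and adjusted p = 0.506 with an estimated correlation). Id1 had 155 fragments against 3 (ratio 56.3, 18.9 to 276), with a fitted log2 fold change of 5.68 that ran from 4.73 to 9.39 with libraries left out. Bhlhe41 rose by 3.84 ± 0.31, Lyl1 by 1.71 and Mxd1 by 1.66, while Bhlhe40 fell by 0.74. Camera did not call this list without MIG-E47 replicate 1 (0.0682) or replicate 2 (0.167). The list holds Tcf3, the introduced gene, and Id2. Without both, an alternative chosen after the data were seen, 7 of 16 rose and 4 fell, the median was 0.40 and camera did not call the list (0.0516).

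Of 31 effector and terminal differentiation genes, 2 rose, 14 fell and 15 were not called (2 and 15 adjusted over the list alone). Their median was −0.44 (camera adjusted p = 0.000318, and adjusted p = 0.939 with an estimated correlation). Nkg7, a granule protein gene, fell from 279 ± 30.3 to 136 ± 15.9 CPM (−1.03 ± 0.12), Ccl5 from 30.4 ± 7.1 to 9.99 ± 2.46 CPM, and S100a6 from 846 to 450 CPM (−0.91), whereas Prf1 rose. Of 22 glycolysis genes, 12 fell, 0 rose and 10 were not called (14 fell adjusted over the list alone; 1 was higher at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 higher), with a median of −0.42 (camera adjusted p = 0.000979, and adjusted p = 0.939 with an estimated correlation), and a median of −0.25 without MIG replicate 2. The aldolase gene Aldoc fell from 158 ± 33.5 to 64.8 ± 9.98 CPM (−1.28 ± 0.16, adjusted p = 0.000349) and the glucose transporter gene Slc2a3 from 331 to 233 CPM (−0.51). Hk2 (−0.70, adjusted p = 0.00443) was not called without MIG-E47 replicate 1 (0.059). Pgk1 (−0.61, adjusted p = 0.021) was not called without MIG-E47 replicate 1 (0.186) or MIG replicate 2 (0.0534).

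Of 27 memory and naive-like genes, 6 rose, 7 fell and 14 were not called (7 and 10 adjusted over the list alone), so the list had no common direction: its median was −0.15 and its mean 0.26, and camera pointed up (adjusted p = 0.753). Il6ra, a receptor chain for IL-6, rose from 1.11 to 115 CPM (6.69), Nsg2 by 2.31 and the repressor gene Zeb1 by 1.24, while S1pr1, which guides exit from lymph nodes, fell by 1.04. Markers of other cell types gave purity values. Bst2, the most abundant dendritic-cell marker and also an interferon-stimulated gene, rose from 97.6 ± 6.04 to 199 ± 20.5 CPM (1.03 ± 0.11, adjusted p = 0.000129). Ctla4, the most abundant marker of CD4 T cells and also made by activated CD8 T cells, fell from 276 ± 9.67 to 176 ± 14.2 CPM (−0.65 ± 0.09, adjusted p = 0.000963). The monocyte marker Itgam was at 3.12 against 4.14 CPM (−0.40) and not called with all 6 libraries. Its log2 fold change was −0.86 without MIG replicate 2, where it was called, and 0.26 without MIG replicate 1. The B-cell marker Cd79b (19.6 against 26.9 CPM, −0.45, adjusted p = 0.0451) was not called without MIG replicate 1 (0.143), either MIG-E47 library (0.0744 and 0.233) or either MIG-ID2 library (0.0738 and 0.0768). The erythroid gene Slc4a1 had 185 fragments with E47 and 0 in MIG, at least 33.5-fold higher.

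**Figure D2:**
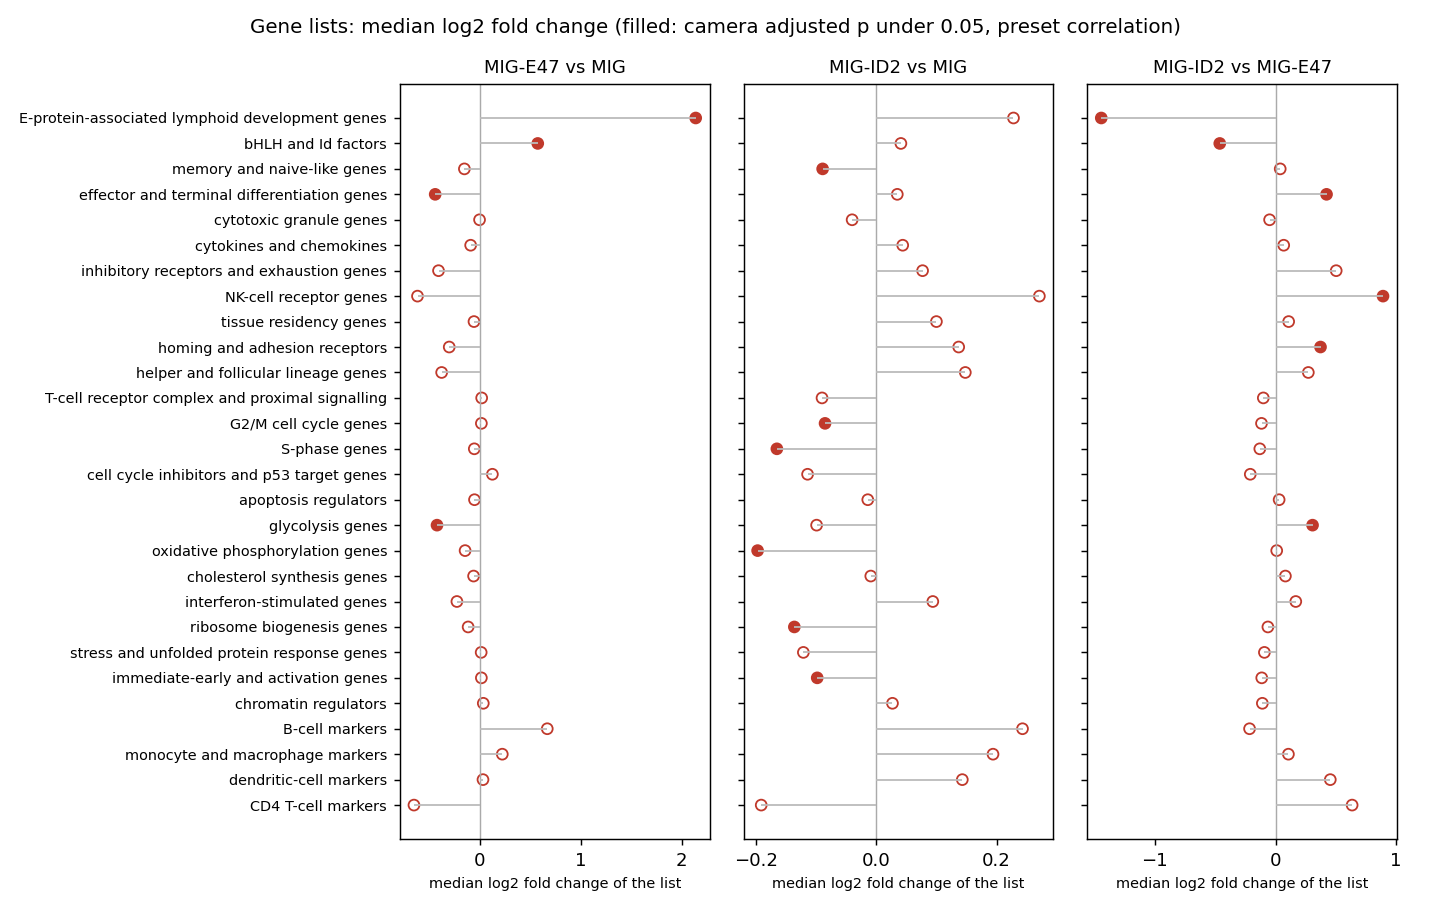
Median log2 fold change of the tested members of each of 28 gene lists, with 1 panel per comparison and filled points where camera called the list at the preset correlation. The x axes differ in range: the lists called between MIG-ID2 and MIG have medians from −0.20 to −0.09, and those of MIG-E47 against MIG from −0.44 to 2.14.

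The comparison of MIG-ID2 with MIG asks which genes respond to added ID2. At the depth of 2 libraries per group, few did: 6 of 12524 tested genes changed, 2 higher and 4 lower. Id2, the introduced gene, was at 841 ± 111 against 86.5 ± 16.6 CPM (3.28 ± 0.15, adjusted p = 7.66e-05), and its fragments can come from the vector. Id3 fell from 36.5 ± 0.143 to 13.2 ± 2.45 CPM (−1.46 ± 0.14, adjusted p = 0.0169), opposite to its rise with E47. Tcf3 was at 224 ± 6.02 against 219 ± 21.3 CPM (0.03, adjusted p = 0.958).

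The noncoding RNA Xist, which silences an X chromosome, rose from 297 ± 22.6 to 632 ± 24.4 CPM (1.09 ± 0.13, adjusted p = 0.0327), with its antisense gene not separable. The muscle glycogen phosphorylase gene Pygm fell from 23.1 ± 2.26 to 9.45 ± 1.39 CPM (−1.28 ± 0.15, adjusted p = 0.0327), and the GTPase gene Arl5c from 70.6 ± 1.64 to 33 ± 4.51 CPM (−1.10 ± 0.12, adjusted p = 0.0256). The pseudogene Bambi-ps1 fell from 18.9 ± 2.05 to 7.87 ± 1.2 CPM (−1.27 ± 0.14, adjusted p = 0.0327), uncertain where fragments are shared with Bambi. In all 6 genes both MIG-ID2 libraries lay on the same side of both MIG libraries. Id2 was called without any single library. The fits that left out MIG-E47 replicate 1, MIG-E47 replicate 2 and MIG-ID2 replicate 2 called 1 gene each, and that without MIG-ID2 replicate 1 called 2, with adjusted p-values for Id3 of 0.0607, 0.0732 and 0.122 in the first 3. Xist, Pygm, Arl5c and Bambi-ps1 were called in none of these 4 fits (adjusted p from 0.0607 to 0.448), although with libraries left out their log2 fold changes ran from 1.01 to 1.17, −1.45 to −1.15, −1.25 to −0.97 and −1.43 to −1.12. Without MIG replicate 1 the count was 776 and without MIG replicate 2 it was 15. At an unadjusted p under 0.05 there were 1072 genes, DESeq2 called 44, a fit without the low-count filter 45, the replicate block 23, scaling by library size alone 10 and a fit on the compared groups alone 1.

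Of the other anchor genes none was called by edgeR. Il7r was at 217 ± 8.22 against 151 ± 29.7 CPM (0.52, adjusted p = 0.383). Zeb2, from the list of effector and terminal differentiation genes, was at 3.8 ± 0.131 against 2.29 ± 0.0251 CPM (0.73, adjusted p = 0.563). Prdm1 was at 0.24, Bcl2 at 0.19, Tbx21 at 0.08, Bach2 at 0.07, Prf1 at 0.04, Ccr7 at 0.00, Gzmb and Eomes at −0.11 and Tcf7 at −0.28. Without MIG replicate 1, Il7r (0.73, adjusted p = 0.0161) was called. Klrg1, Ifng and Cx3cr1 had at most 9 fragments per group. Cd79b (−0.22), Itgam (0.07), Bst2 (−0.25) and Ctla4 (−0.19), the most abundant markers of other cell types, were not called, and Slc4a1 had 0 fragments in both groups.

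Camera called 6 lists lower with ID2, with 0 or 1 called genes in each, and in all 6 the adjusted p = 0.645 with an estimated correlation. Of 25 oxidative phosphorylation genes 0 were called (0 adjusted over the list alone), with a median of −0.20 (camera adjusted p = 6.77e-07), and Atp5b, an ATP synthase subunit, was at −0.20. Of 25 S-phase genes 0 were called (0 adjusted over the list alone), with a median of −0.17 (adjusted p = 3.97e-05) and the replication clamp gene Pcna at −0.18. Of 25 ribosome biogenesis genes 0 were called (0 adjusted over the list alone), with a median of −0.14 (adjusted p = 0.0051) and the nucleolar gene Npm1 at −0.11. Of 25 G2/M genes 0 were called (0 adjusted over the list alone), with a median of −0.09 (adjusted p = 0.0305), while Mki67 was at 0.14. Of 25 immediate-early genes 0 were called and 1 fell adjusted over the list alone, with a median of −0.10 and a mean of −0.288 (adjusted p = 0.0305) and Jund at −0.48, which DESeq2 called (adjusted p = 0.0155). Of 27 memory and naive-like genes 1 fell, Id3 (1 rose and 2 fell adjusted over the list alone), with a median of −0.09 (adjusted p = 0.0408) that was −0.02 with the replicate block and 0.00 without MIG-ID2 replicate 1. At an unadjusted p under 0.05, edgeR had 3 oxidative phosphorylation, 3 S-phase, 2 ribosome biogenesis, 2 G2/M and 4 immediate-early genes lower and 0 higher, and of these lists DESeq2 called 1 gene, Jund, and limma-voom 0. With scaling by library size alone, where the median of all genes was 0.078, the list medians were nearer 0: −0.12 for oxidative phosphorylation, −0.09 for S-phase, −0.06 for ribosome biogenesis, −0.01 for G2/M and −0.02 for immediate-early and for memory genes. The medians of 5 of these lists depended on single libraries. Without MIG replicate 2, which stood apart on the second principal component, oxidative phosphorylation genes had a median of −0.06 (adjusted p = 0.0976), ribosome biogenesis genes one of 0.04 (adjusted p = 0.496), immediate-early genes one of −0.17 and memory genes one of −0.22. Without MIG replicate 1 these medians were −0.32, −0.27, −0.05 and −0.08, and without MIG-ID2 replicate 2 that of G2/M genes was −0.02, whereas S-phase genes stayed between −0.18 and −0.14 with each library left out in turn. Without MIG replicate 1 the adjusted p was 0.524 for memory, 0.234 for G2/M and 0.292 for immediate-early genes, and Atp5b (0.0456) and Jund (0.022) were called. Without a MIG-E47 or MIG-ID2 library the lowest-ranked of these lists were also lost, at 0.122 (MIG-E47 replicate 1), 0.152 (MIG-E47 replicate 2) and 0.216 (MIG-ID2 replicate 1) for memory and 0.117, 0.127 and 0.0935 for immediate-early genes, 0.0705 for ribosome biogenesis without MIG-ID2 replicate 1 and 0.115 for G2/M without MIG-ID2 replicate 2.

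The comparison of MIG-ID2 with MIG-E47 sets the E-protein inhibitor against the E protein. A difference here can come from either construct, and only 6 genes were called between MIG-ID2 and MIG. Expression differed broadly again: 3694 of 12524 genes differed (29.5%), 1503 higher and 2191 lower with ID2, and of 1536 that differed at least 2-fold 376 were higher and 1160 lower. Cells with ID2 had more Il7r, Ccr7, Ccl5 and Klrd1 transcripts and less Id3, Rag1 and Prf1 than cells with E47. With upper-quartile scaling the median of all genes was 0.136, against 0.013 with TMM, and 58.4% of 4364 called genes were higher, against 40.7% of those called with TMM. Without MIG-E47 replicate 1 the count was 2028, without MIG-ID2 replicate 1 2061 and without MIG-ID2 replicate 2 2257.

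Tcf3 was lower with ID2 by −3.45 ± 0.15 (adjusted p = 1.05e-06) and Id2 higher by 1.39 ± 0.14 (841 ± 111 against 320 ± 11.6 CPM, adjusted p = 0.000116). Id3 was at 13.2 ± 2.45 against 166 ± 14.3 CPM (−3.64 ± 0.14, adjusted p = 9.74e-07). Il7r was higher with ID2 at 217 ± 8.22 against 79.1 ± 1.5 CPM (1.45 ± 0.13, adjusted p = 6.21e-05), Ccr7 by 1.00 ± 0.12 (adjusted p = 0.000253) and Tbx21 by 0.83 ± 0.13 (adjusted p = 0.00152), while Prf1 was lower (−1.33 ± 0.19, adjusted p = 0.000766). Bach2 (0.78, adjusted p = 0.00751) was not called without MIG-E47 replicate 1 (0.0598) or 2 (0.062). Prdm1 (0.36, adjusted p = 0.0443) was not called without either MIG-E47 library (0.282 and 0.0633), either MIG-ID2 library (0.11 and 0.29) or by DESeq2 (0.0859). Zeb2 (0.86, adjusted p = 0.0376) was not called without MIG-E47 replicate 1 (0.232), either MIG-ID2 library (0.175 and 0.127) or by DESeq2 (0.104). Tcf7 (−0.20), Eomes (0.04), Bcl2 (0.53, adjusted p = 0.0753) and Gzmb (0.11) were not called, and Bcl2 was called without MIG replicate 1 (0.00815) or 2 (0.0083), by DESeq2 (0.0232) and with upper-quartile scaling (0.0292).

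Named genes higher with ID2 were led by Gucy1a3, a subunit of soluble guanylate cyclase (2.98 ± 0.46, adjusted p = 0.00119), and Ccl5 at 58.4 ± 5.58 against 9.99 ± 2.46 CPM (2.55 ± 0.2, adjusted p = 2.73e-05). They were followed by Copz2 (2.45), Spred3 (2.17), Sncb (2.06), Tfr2 (2.04), Nhsl2 (2.02) and Gbp10 (1.99, from a family of near-identical genes and so uncertain). Nhsl2 was not called without MIG-E47 replicate 1 (0.0946) or 2 (0.0817). Of genes lower with ID2, 108 had 0 fragments in both MIG-ID2 libraries. Among them Col17a1 was at least 447-fold lower (221-fold without MIG-E47 replicate 1 and 673-fold without replicate 2), Pou3f1 403-fold, Efhd1 267-fold, Tmem145 225-fold, Rag1 199-fold, Slit3 193-fold, and Lhx3 and Usp43 185-fold, all as lower bounds, with adjusted p-values from 3.98e-06 to 0.000286. Col17a1 and Pou3f1 had 0 fragments in MIG as well, and Rag1 had 1. For these genes the difference repeats the rise with E47 against MIG and shows no lowering by ID2.

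Of 23 E-protein-associated lymphoid genes, 14 were lower, 2 higher and 7 not called (15 lower and 2 higher adjusted over the list alone), with a median of −1.44 (camera adjusted p = 4.22e-11, and adjusted p = 0.769 with an estimated correlation). Gfi1b was at least 56.1-fold lower, and Hes1 had 2 fragments against 707 (ratio 424, 117 to 3510). Of 18 basic helix-loop-helix and Id factors, 9 were lower and 5 higher (10 and 7 adjusted over the list alone, 7 and 7 with upper-quartile scaling, and 7 and 6 with scaling by library size alone), with a median of −0.46 (adjusted p = 0.00554, and adjusted p = 0.769 with an estimated correlation), Id1 at −5.11 ± 0.66 (5 fragments against 155, −4.33 without MIG-ID2 replicate 1 and −6.45 without MIG-ID2 replicate 2) and Bhlhe41 at −3.80. Without Tcf3 and Id2, 8 of 16 were lower and 4 higher (adjusted p = 0.0165). Of 31 effector genes, 18 were higher and 3 lower (19 and 3 adjusted over the list alone), with a median of 0.42 (adjusted p = 0.000474, and adjusted p = 0.78 with an estimated correlation). The IL-12 receptor gene Il12rb2 was higher (1.5 ± 0.27) and the granzyme gene Gzma lower (193 ± 34.3 against 542 ± 118 CPM, −1.49 ± 0.18).

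Of 11 NK-cell receptor genes, 4 were higher and 0 lower (5 and 0 adjusted over the list alone; 0 were lower at an unadjusted p under 0.05, by DESeq2 or by limma-voom), with a median of 0.89 (camera adjusted p = 0.0362, adjusted p = 0.78 with an estimated correlation and 0.0555 with fry). Klrd1 was higher by 1.13 ± 0.12 and Klrk1 by 0.89 ± 0.14, both encoding lectin-like receptors. Of 30 homing and adhesion receptors, 14 were higher and 6 lower (15 and 6 adjusted over the list alone), with a median of 0.37 (adjusted p = 0.0363, and adjusted p = 0.78 with an estimated correlation). The chemokine receptor genes Ccr10 (−4.32) and Cxcr5 (−3.53 ± 0.51, −2.84 without MIG-ID2 replicate 1 and −4.67 without MIG-ID2 replicate 2) were lower and Ccr1 (1.68) was higher. Of 22 glycolysis genes, 7 were higher and 1 lower (9 and 1 adjusted over the list alone, and 14 and 0 with upper-quartile scaling), with a median of 0.31 (adjusted p = 0.00959, and adjusted p = 0.912 with an estimated correlation), and a median of 0.19 without MIG-E47 replicate 1. Among them Aldoc was at 1.18 ± 0.16, Slc2a3 at 0.94 ± 0.09 and Hk2 at 0.75 ± 0.13. Without MIG-E47 replicate 1 the adjusted p was 0.117 for each of these 3 lists, and homing receptors were also lost without MIG-E47 replicate 2 (0.148), without MIG-ID2 replicate 2 (0.0725) and with the replicate block (0.1). Of cell type markers, Bst2 was lower with ID2 (−1.28 ± 0.11, adjusted p = 3.52e-05), Cd79b (0.23) and Itgam (0.47) were not called, and Slc4a1 was at least 36.5-fold lower. Ctla4 was higher (0.46 ± 0.09, adjusted p = 0.00595) and not called without MIG-E47 replicate 1 (0.0851) or either MIG-ID2 library (0.0555 and 0.0739). Of 7 CD4 T-cell markers 5 were higher and 2 lower (5 and 2 adjusted over the list alone), and camera did not call the list (0.381), while fry called it up (adjusted p = 0.0279). Fry also called inhibitory receptor genes up (9 of 21 higher and 3 lower) and tissue residency, apoptosis and immediate-early genes down (adjusted p = 0.0279 each), none of which camera called.

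The relation between the comparisons asks whether ID2 moves the genes that E47 moves, and in which direction. Of the 4 genes that fell with ID2, Id3 (2.19), Arl5c (1.35) and Bambi-ps1 (0.97) rose with E47, and Pygm (−0.23) was not called there. Across 12524 genes, which are not independent replicates, the log2 fold changes against MIG had a Pearson r of 0.164 and a Spearman correlation of 0.153. Both comparisons use the same MIG libraries, so these values were set beside 50 simulations with the fitted E47 change and no ID2 change, which gave medians of 0.123 (0.0644 to 0.181) and 0.168 (0.142 to 0.196). The covariance was 0.0868 against 0.0562 (0.0307 to 0.087), so all 3 values lay in the ranges of these 50 simulations. The first plan used 100 simulations of unchanged groups, without the E47 change. They gave medians of 0.501 (0.472 to 0.566) for Pearson r, 0.466 (0.441 to 0.482) for Spearman and 0.0275 (0.0252 to 0.0337) for covariance. The observed correlations lay below these ranges and the observed covariance above. A set of 10292 genes with a mean of at least 50 normalised fragments in MIG was chosen after the data were seen. There r was 0.0791 against 0.146 (0.118 to 0.182), under all 50 simulations. This r moved with single libraries. It was 0.345 without MIG replicate 1, 0.0931 without MIG replicate 2, 0.123 without MIG-ID2 replicate 1 and 0.0135 without MIG-ID2 replicate 2. The simulations held 2 libraries per group, so values without a library have no simulated range of their own. The simulations give each group the same spread, although the MIG libraries differed more than the others. Across all genes Pearson r was 0.368 without MIG replicate 1, 0.267 without MIG replicate 2, 0.069 without MIG-ID2 replicate 1, 0.092 without MIG-ID2 replicate 2 and 0.095 on log2(FPKM + 1), and the covariance was 0.31 without MIG replicate 1, 0.191 without MIG replicate 2 and 0.0482 without MIG-ID2 replicate 1.

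At an unadjusted p under 0.05, 715 genes were higher and 357 lower with ID2. Genes higher with E47 included 61 of the lower ones, against 54 (34 to 69) in the 50 simulations, and 166 of the higher ones, against 102 (84 to 125). Genes lower with E47 included 67 of the higher ones, against 22 (15 to 36), and 41 of the lower ones, against 85 (65 to 102). Independent lists of the observed sizes would share 63.3, 126.8, 76.7 and 38.3 genes in this order, so by that measure opposed genes were not in excess. That measure ignores the shared MIG libraries, and the simulations were not matched to the 715 and 357 genes. The observed counts moved widely with single libraries. Without MIG replicate 1 they were 102, 670, 123 and 922 in this order, without MIG replicate 2 101, 131, 57 and 149, without MIG-ID2 replicate 1 31, 91, 23 and 8, and without MIG-ID2 replicate 2 44, 41, 26 and 7. Of the 209 genes at least 2-fold lower with E47, 65.6% lay above 0 with ID2, against 35% (30.3 to 38.7%) in the simulations, and this share was 38.2% without MIG replicate 1 and 46.9% without MIG replicate 2. Of the 1202 genes at least 2-fold higher with E47, 40.7% lay below 0 with ID2, against 42.2% simulated (38.8 to 45.3%), and 27.9% without MIG replicate 1.

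**Figure D3:**
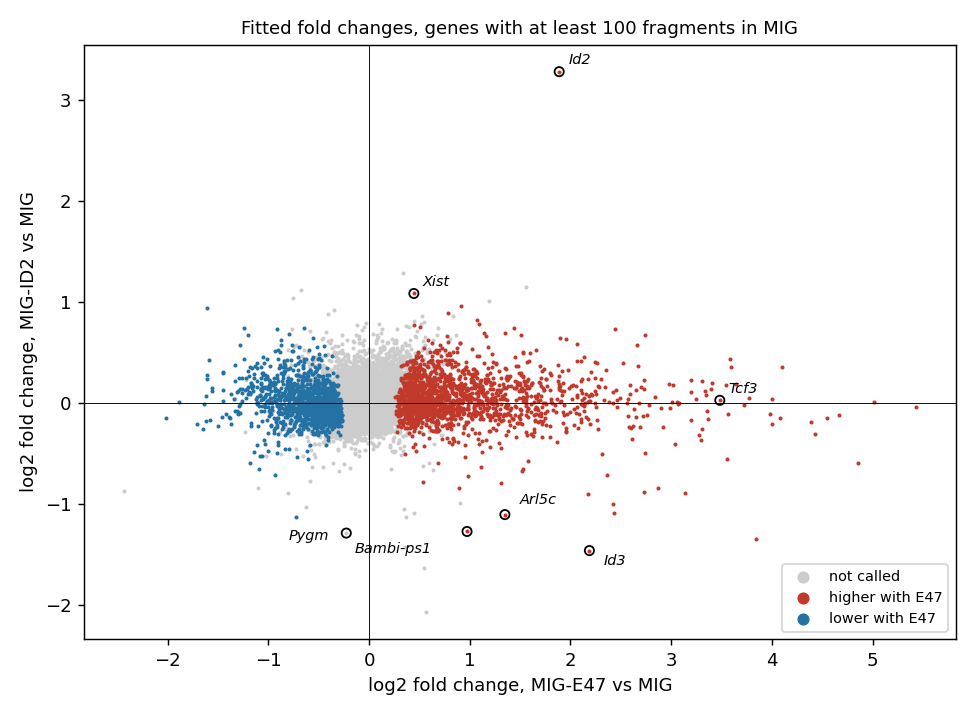
Log2 fold change with ID2 (y axis) against that with E47 (x axis), both relative to MIG, with 1 point per gene that had at least 100 fragments in MIG, coloured by the call with E47. Id3, Arl5c and Bambi-ps1 lie to the right of and below the origin, and Id2 lies above all other points.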

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

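Alternatives were chosen before the data were examined, except the list of basic helix-loop-helix factors without Tcf3 and Id2 and the relation in 10292 genes with more fragments (Pearson r of 0.079). The 50 simulations of the relation were not in the first plan, which named 100 of unchanged groups. Of 417 called results for single genes, 357 kept their direction and call under every alternative tool, scaling, filter and block, 60 lost the call under at least 1, and 191 lost it without at least 1 library; none changed direction. Among results that were not called, 16 changed direction without a library. A minimum of 2-fold left 1411 genes for MIG-E47 against MIG and 1536 for MIG-ID2 against MIG-E47. The 6 genes of MIG-ID2 against MIG became 10 with scaling by library size alone, 44 with DESeq2, 45 without the filter and 1 on the compared groups alone (fewer libraries). The causes of these shifts were not tested. Leaving out 1 library gave 1736 to 4954 genes for MIG-E47 against MIG, 1 to 776 for MIG-ID2 against MIG, 2028 to 4940 for MIG-ID2 against MIG-E47, and a Pearson r of 0.069 to 0.368 between the comparisons with MIG. With the replicate number as a block the counts were 3781, 23 and 3967 and r was 0.152. The labels state no pairing, so the numbers were not taken as pairs. Same-numbered libraries had deviations that correlated at 0.21, 0.03 and 0.15, which does not decide whether they are pairs. Under the block camera did not call the memory and immediate-early lists with ID2 (adjusted p of 0.166 and 0.0915).

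With libraries left out in turn, the log2 fold changes of MIG-E47 against MIG ranged from −0.21 to 0.06 for Tcf7, −1.11 to 0.87 for Eomes, −0.47 to 0.08 for Gzmb, −0.50 to 0.18 for Zeb2 and −0.86 to 0.26 for Itgam. Those of MIG-ID2 against MIG ranged from −0.07 to 0.13 for Tcf3, −0.75 to 0.91 for Eomes, −0.09 to 0.52 for Bcl2, −0.19 to 0.38 for Bach2, −0.36 to 0.19 for Gzmb, −0.27 to 0.29 for Prf1, −0.07 to 0.26 for Tbx21, −0.29 to 0.08 for Npm1 and −0.38 to 0.74 for Itgam. Those of MIG-ID2 against MIG-E47 ranged from −0.60 to 0.99 for Eomes and −0.08 to 0.33 for Gzmb. List medians with ID2 against MIG ranged from −0.22 to 0.00 for memory genes, with camera pointing up without MIG replicate 1 (−0.08), and from −0.27 to 0.04 for ribosome biogenesis. None of the 16 list calls held with an estimated correlation, and fry kept those of the E-protein-associated list (0.0253), of basic helix-loop-helix factors (0.0155) with E47 against MIG, and of these (0.0246 each) and effector genes (0.0377) with ID2 against E47. The depth of the libraries limits what can be said of genes such as Klrg1, Ifng and Cx3cr1, which had at most 9 fragments per group.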

Other observations

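With E47, several further lists split into members that rose and members that fell, and camera called none of them against MIG (adjusted p from 0.0855 to 0.934). Fry called tissue residency (adjusted p = 0.0253), apoptosis (0.0393) and immediate-early genes (0.0435) up and CD4 T-cell markers (0.0253) down. The medians of the first 3 were −0.06, −0.05 and 0.02. For the other lists neither camera nor fry called a direction, and the counts of called genes are given. Of 21 inhibitory receptor genes, 3 rose, 7 fell and 11 were not called (3 and 8 adjusted over the list alone): the activation-induced nuclear receptor genes Nr4a1 (7.27 to 57.8 CPM) and Nr4a3 (1.66 to 18.7 CPM) were higher and Lag3, a receptor that restrains T cells, fell from 308 to 154 CPM. Of 19 tissue residency genes, 7 rose and 5 fell (7 and 5 adjusted over the list alone). Cdh1, which encodes E-cadherin, rose from 0.964 to 179 CPM (7.53), and the chemokine receptor gene Cxcr6 fell from 108 to 44.9 CPM (−1.26). Of 30 homing receptors, 6 rose and 11 fell (6 and 11 adjusted over the list alone), with Ccr10 (3.40) and Ccr4 (1.48) higher. Of 23 apoptosis regulators, 5 rose and 2 fell (5 and 2 adjusted over the list alone, and 4 and 4 with upper-quartile scaling), among them both the protective Bcl2l1 (41.6 to 161 CPM) and the death-promoting Bcl2l11 (30.3 to 83.2 CPM), which were higher. Of 28 chromatin regulators, 11 rose and 1 fell (12 and 3 adjusted over the list alone), including the DNA methyltransferase gene Dnmt3a (45.7 to 126 CPM, 1.46). Their median was 0.04, and −0.06 with upper-quartile scaling. Of 26 T-cell receptor complex and signalling genes, 8 rose and 4 fell (9 and 7 adjusted over the list alone), with Cd8a (0.65) and Lat (0.69) higher. Their median was 0.02, and with upper-quartile scaling it was −0.08, with 5 that rose and 8 that fell.

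Few genes of proliferation and biosynthesis were called with E47 after TMM scaling. Among 25 G2/M genes 0 were called by edgeR (0 adjusted over the list alone), DESeq2 or limma-voom, and 2 were higher at an unadjusted p under 0.05, and among 25 S-phase genes 2 rose and 1 fell (1 and 1). Of 25 genes of cell cycle inhibition and p53 response, 3 rose and 3 fell, and the same numbers held adjusted over the list alone. Oxidative phosphorylation had 1 of 25 higher (0), ribosome biogenesis 1 of 25 lower (0), and cholesterol synthesis 3 of 24 higher (3), among them Fdft1 (0.94) and Insig1 (0.87). With upper-quartile scaling more fell: 0 S-phase genes rose and 4 fell, 1 oxidative phosphorylation gene rose and 9 fell, and 3 cholesterol synthesis genes rose and 6 fell. Of 26 interferon-stimulated genes 5 rose and 7 fell (7 and 7), with Irf7 at 20.1 and 56.8 CPM. Of 21 stress genes 3 rose and 1 fell (3 and 1), with the secretory-pathway regulator Xbp1 at 80.1 and 226 CPM, and of 25 immediate-early genes 4 rose and 6 fell (4 and 6), with Dusp4 at 1.53 and Klf6 at −0.80. Of 21 cytotoxic granule genes 3 rose and 5 fell (5 and 5), with the cathepsin gene Ctsw at −1.12. Of 12 cytokine genes 2 rose and 2 fell (2 and 2), with Tnfsf14 at 2.57. Of 11 NK-cell receptor genes 3 fell and 0 rose (3 and 1), with Klrd1 at −0.94, and of 13 helper and follicular genes 3 rose and 5 fell (4 and 5), with Icos at −0.83. Of marker lists, B cells had 1 of 12 higher and 1 lower (1 and 0), monocytes 0 of 4 called (0; 1 higher at an unadjusted p under 0.05, 1 by limma-voom, 0 by DESeq2), dendritic cells 1 of 11 higher and 5 lower (1 and 5), and CD4 T cells 1 of 7 higher and 5 lower (1 and 5), Cd4 itself rising from 0.601 to 8.66 CPM (3.84). The median, the mean and the direction given by camera differed in sign for cytotoxic granule, cytokine, inhibitory receptor, tissue residency, helper, T-cell receptor, G2/M, S-phase, apoptosis, cholesterol, interferon, monocyte, dendritic and CD4 lists. With ID2, the E-protein-associated list had a median of 0.23 against MIG and a mean of −0.17, with camera pointing down (adjusted p = 0.12). Rag1 had 1016 fragments with E47 while its partner Rag2 had 1, and Slc4a1 had 185 while the hemoglobin gene Hba-a1 had 2.

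Of the tests that follow, those on marker genes, on background fragments and on Y-linked genes were chosen only after the results they bear on had been seen. The 125 genes with no fragment in MIG that rose with E47 reached a summed 1090 CPM with E47, were found in both MIG-E47 libraries and had under 4 fragments with ID2 in 120 cases. RNA of erythroid cells or keratinocytes is argued against by 9 of their marker transcripts, which summed to 0.102 CPM, 0.00932% of that level. An even background of DNA is argued against by the 8986 genes silent in MIG, of which 1.89% had at least 10 fragments with E47. A trend on GC content and length explained 4% of the variance, and its removal moved the median log2 excess over the floor from 3.83 to 3.65. At least 2-fold above the floor were 100% of the 125 genes before and 100% after. They were chosen as called genes with 0 fragments in MIG, so that share could hardly fall and does not decide. RNA of thymocytes stays open, although per the protocols the cells were sorted for CD8 and for the GFP of the vector. Of 6 thymocyte markers 4 were called higher, namely Rag1 (1016 fragments against 1), Cd4 (3.84), Dntt (3.14) and Ptcra (2.14), while Rag2 had 1 fragment with E47 and Cd24a was at −0.16. E47 in T cells may raise such genes too, so these markers do not decide. Markers of B cells, monocytes, dendritic cells and CD4 T cells were given above, and cell types beyond these were not checked. A hypothesis beside these is that E47 at this level may activate genes otherwise silent in these cells, and whether E47 binds them was not analysed here.

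Xist was higher in both MIG-ID2 libraries (614 and 649 CPM) than in the MIG libraries (281 and 313 CPM), and the MIG-E47 libraries were at 456 and 353 CPM. A different mix of male and female cells is argued against by the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y, which had 0 fragments in all 6 libraries. A general rise of the X chromosome is argued against by 393 X-linked genes, whose median log2 fold change was 0.057 above that of 12046 autosomal genes. A difference in culture state or source animal between groups was not tested and stays open beside a response to ID2, so an effect of ID2 on Xist may be raised only as a hypothesis. When either MIG-ID2 library or either MIG-E47 library was left out, the log2 fold change stayed at 1.04 to 1.12, against 1.09 ± 0.13 with all 6, although the call ended. Without either MIG library the call was kept. The MIG replicates differed more than those of the other groups, so leaving 1 of them out also takes the largest spread from the fit. These fits therefore do not decide whether fewer libraries account for the loss of the call.

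Genes at least 2-fold lower with E47 tended to lie above MIG with ID2 (65.6% of 209). Chance values of the shared MIG libraries push this share down, and with MIG-E47 set against MIG replicate 2 and MIG-ID2 against MIG replicate 1 it was 75.9% of 237 genes, against 52% of all genes. The reverse arrangement gave 81.1% of 227 genes, against 51.4% of all genes. No reciprocal excess was seen: of genes at least 2-fold higher with E47, 46.5% and 36.3% lay below MIG with ID2 in these arrangements. Genes near 0 in MIG can hardly lie below it and hold these shares down, so they do not decide on a reciprocal. Against both MIG libraries, 236 genes that rose with E47 had under 4 MIG fragments, 125 of them 0. With a single MIG library used for both comparisons the share of lowered genes above MIG was 38.2% (replicate 2 kept) and 46.9% (replicate 1 kept). There the chance values of 1 library enter both comparisons, and no simulation was run for that case. A hypothesis is that ID2 may slightly raise genes that E47 lowers, but each arrangement rests on 1 MIG library, and culture differences between the MIG libraries, which lie at 10.33 and −28.74 on the second principal component, stay open.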
